A study of Homo sapiens with 5 samples.

How the data were processed

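The deposited files hold UMI counts per gene and cell barcode, and the values are whole counts. Per the submitters' processing notes, the authors made these counts with Cell Ranger 2.1 against hg38 from 10x Chromium 3′ v2 libraries. The files list 33694 genes. Positions were taken from GENCODE 29 on GRCh38 by gene identifier, and the annotation used for the files may be another release. The deposited matrices already hold called cells. Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. This kept 4611 of 4614 bulk barcodes, 2183 of 2207 CD44low CD24high barcodes and 5417 of 5420 BT-549 barcodes. Median mitochondrial shares were 2.67%, 2.85%, 2.33%, 2.56% and 2.43% for bulk, CD44low CD24high, CD44high CD24low experiments 1 and 2, and BT-549. No barcode was shared with the same total between libraries. Scrublet marked 2, 7, 3, 2 and 1 cells, too few for libraries of this size, so it has not worked here and doublets were not removed. Leaving out cells above 2 times their library's median UMIs was used as a stand-in.

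Counts were summed over cells per library. Tests used edgeR's quasi-likelihood test on the 4 HMLE libraries with TMM factors and Benjamini-Hochberg adjustment at 0.05. The model has 1 residual degree of freedom, which comes from the 2 CD44high CD24low libraries, and its biological coefficient of variation was 5.34%. Each lone library is assumed to vary as that pair does. The chi-square per degree of freedom between these libraries was 33.6 over 15567 genes, so counting error alone does not describe them. With a median of 19.1 prior degrees of freedom, each test rests mostly on a variance shared across genes and little on that gene's own spread. Comparisons of 1 library with 1 library used log2(CPM + 1) and exact Poisson intervals, which cover counting error only. Genes with no count on one side are given as at least a fold, from a floor of 3 counts. The 28 gene lists were written before the data were examined, as were the filters, comparisons and most alternatives. List percentiles are among 10000 random lists of the same size matched on mean expression. Genes named for large rises and falls had the largest log2 fold changes among those past the test, at 50 CPM or more in the higher group and with the same sign in both CD44high CD24low libraries. In the comparisons of single libraries they had the largest ratios at 100 CPM or more. In each list up to 2 risers and 2 fallers past the test were named, more where 5 or fewer passed, and up to 4 members for BT-549. Some genes are not reported here.

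Clusters came from scanpy with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, for HMLE and BT-549 separately and with each cell thinned to 5000 UMIs. This left out 431 BT-549 cells. In simulated counts with the observed common dispersion, the edgeR test found 20%, 66%, 88% and 100% of 50 genes each changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and called 8 of 15788 unchanged genes. Every gene and library was given that same dispersion. The simulation therefore does not test whether a lone library varies as the pair does, nor the error rate of the calls in the real data. The mixture estimate was off by at most 0.242 percentage points on simulated mixtures. Of 20 random lists each, those shifted by 0.25 log2 had percentiles of 96.4 or more and those not shifted ranged from 0.24 to 99.7, so a single high percentile can also arise without a shift. A simulated chromosome change of -0.415 was recovered as -0.399. The first version of that statistic, a mean of clipped log2 ratios, recovered -0.21 in the same simulation and was replaced by the median. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.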

Results

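Single-cell transcriptomes were collected from 2 human breast lines. HMLE is a line of normal human mammary epithelial cells immortalised with telomerase and SV40 antigens, and BT-549 is a breast carcinoma line. HMLE was profiled as a bulk population (1 library), as a sorted CD44low CD24high population (1 library) and as a sorted CD44high CD24low population (2 libraries, from experiments numbered 1 and 2), and BT-549 was profiled unsorted (1 library). The sort on the surface proteins CD44 and CD24 was meant to enrich for breast stem cells. After filtering, 4611 bulk cells, 2183 CD44low CD24high cells, 1872 and 726 CD44high CD24low cells and 5417 BT-549 cells remained. The summed unique molecular identifier (UMI) counts were 190314776, 52491333, 108667393, 58861153 and 67790628, with medians per cell of 37438, 23906, 47869, 68002.5 and 11731. The CD44high CD24low cells were thus sequenced more deeply, or held more RNA, than the CD44low CD24high cells. Nothing states that the 2 experiments used separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene positions are given on GRCh38 with GENCODE 29.

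The first comparison asked how the CD44high CD24low population differed from the CD44low CD24high population. CD44high CD24low cells had more mesenchymal and matrix transcripts, among them VIM, FN1 and the type VI collagen gene COL6A2, and fewer epithelial junction transcripts, while the basal keratin KRT14 also rose. Genes of the amino acid response, of NF-kB signalling and of hypoxia were higher as well. Part of this difference was carried by a mesenchymal-like cluster that held 26.1% and 25.6% of the CD44high CD24low cells and none of the 2183 CD44low CD24high cells. Of 16192 genes tested, 2142 rose and 2050 fell in the CD44high CD24low libraries at an adjusted p under 0.05, and 711 and 34 of these changed at least 2-fold. With DESeq2, 1236 genes passed and 66.0% of them were higher, against 51.1% with edgeR.

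The transcripts of both sort markers moved with the sort. CD44 (chromosome 11, 35138870 to 35232402), the hyaluronan receptor, rose from 196 CPM (counts scaled to the same total per library) in the CD44low CD24high library to 257 ± 8.06 CPM (SD, n = 2), a log2 fold change of 0.37 (SE 0.067). CD24 (chromosome 6, 106969831 to 106975627), a small glycosylated surface protein, fell from 344 to 183 ± 16.3 CPM (SD, n = 2), a log2 fold change of -0.93 (SE 0.067). Both moved the same way in both experiments, with adjusted p of 3.3e-04 for CD44 and 2.1e-09 for CD24 (edgeR quasi-likelihood test, Benjamini-Hochberg), assuming that the lone CD44low CD24high library varied as the CD44high CD24low pair did. With each cell thinned to 5000 UMIs, a CD24 UMI was found in 79.7% of CD44low CD24high cells and in 53.3% and 57.6% of the CD44high CD24low cells, and without thinning in 97.9%, 94.4% and 95.2%. No HMLE cells known to lack CD24 were at hand, so the part of these shares that came from free RNA is not known. In the separate BT-549 library an EPCAM UMI was found in 0.241% of the 4986 cells that reached 5000 UMIs, with a median of 12245.5 UMIs before thinning, which does not measure background in the HMLE libraries.

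Genes with large rises among those at 50 CPM or more were KCNMA1 (chromosome 10, 76869601 to 77638369), a calcium-activated potassium channel, and SCG5 (chromosome 15), a secretory granule chaperone. KCNMA1 rose from 4.44 to 79.2 ± 2.93 CPM (SD, n = 2), a log2 fold change of 4.14 (SE 0.10), and SCG5 by 3.54 (SE 0.087). The serine protease inhibitor SERPINE2 (chromosome 2) rose by 2.56 (SE 0.073). IGFBP7 (chromosome 4), the stress-responsive NUPR1 (chromosome 16) and the LIM-domain gene FHL1 (chromosome X) rose by 2.34, 2.29 and 2.03. The intermediate filament gene VIM (chromosome 10) rose from 582 to 2277 ± 119 CPM (SD, n = 2), a log2 fold change of 1.95 (SE 0.098), fibronectin (FN1, chromosome 2) by 1.70 and the interferon-induced IFITM3 (chromosome 11) by 1.61. Falls were smaller. The kallikrein KLK5 (chromosome 19) changed by -1.08 (SE 0.061), the heparan sulfate sulfotransferase HS3ST2 (chromosome 16) by -0.97, the imprinted MEST (chromosome 7) by -0.96 and the apical trafficking GTPase RAB25 (chromosome 1) by -0.73. S100A14 and ARTN (chromosome 1) changed by -0.69 and -0.67, CYB5A and HSBP1L1 (chromosome 18) by -0.65 and -0.63, and IGFBP2 (chromosome 2) by -0.63. Among these genes, CD24 included, the largest adjusted p was 6.9e-06 for S100A14 (edgeR quasi-likelihood test, Benjamini-Hochberg, with the lone library assumed to vary as the pair did). Without the mesenchymal-like cluster the rise of KCNMA1 was 1.73 and no longer passed the test (adjusted p = 0.14, edgeR quasi-likelihood, Benjamini-Hochberg, with the lone library assumed to vary as the pair did). The rises of SCG5, SERPINE2, IGFBP7, NUPR1 and FHL1 were then 1.73, 1.19, 0.95, 1.10 and 1.61, and those of VIM, FN1 and IFITM3 0.85, 0.69 and 0.81. KLK5, HS3ST2, MEST and RAB25 then changed by -0.72, -0.77, -0.73 and -0.34. Of the rises, that of SCG5 was not among those found above the level that free RNA of the cluster's cells would add, weighed below. FHL1 lay above that level in both experiments, and SERPINE2 and NUPR1 in experiment 1 only. The rises under 1 were not weighed in this way.

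**Figure D1:**
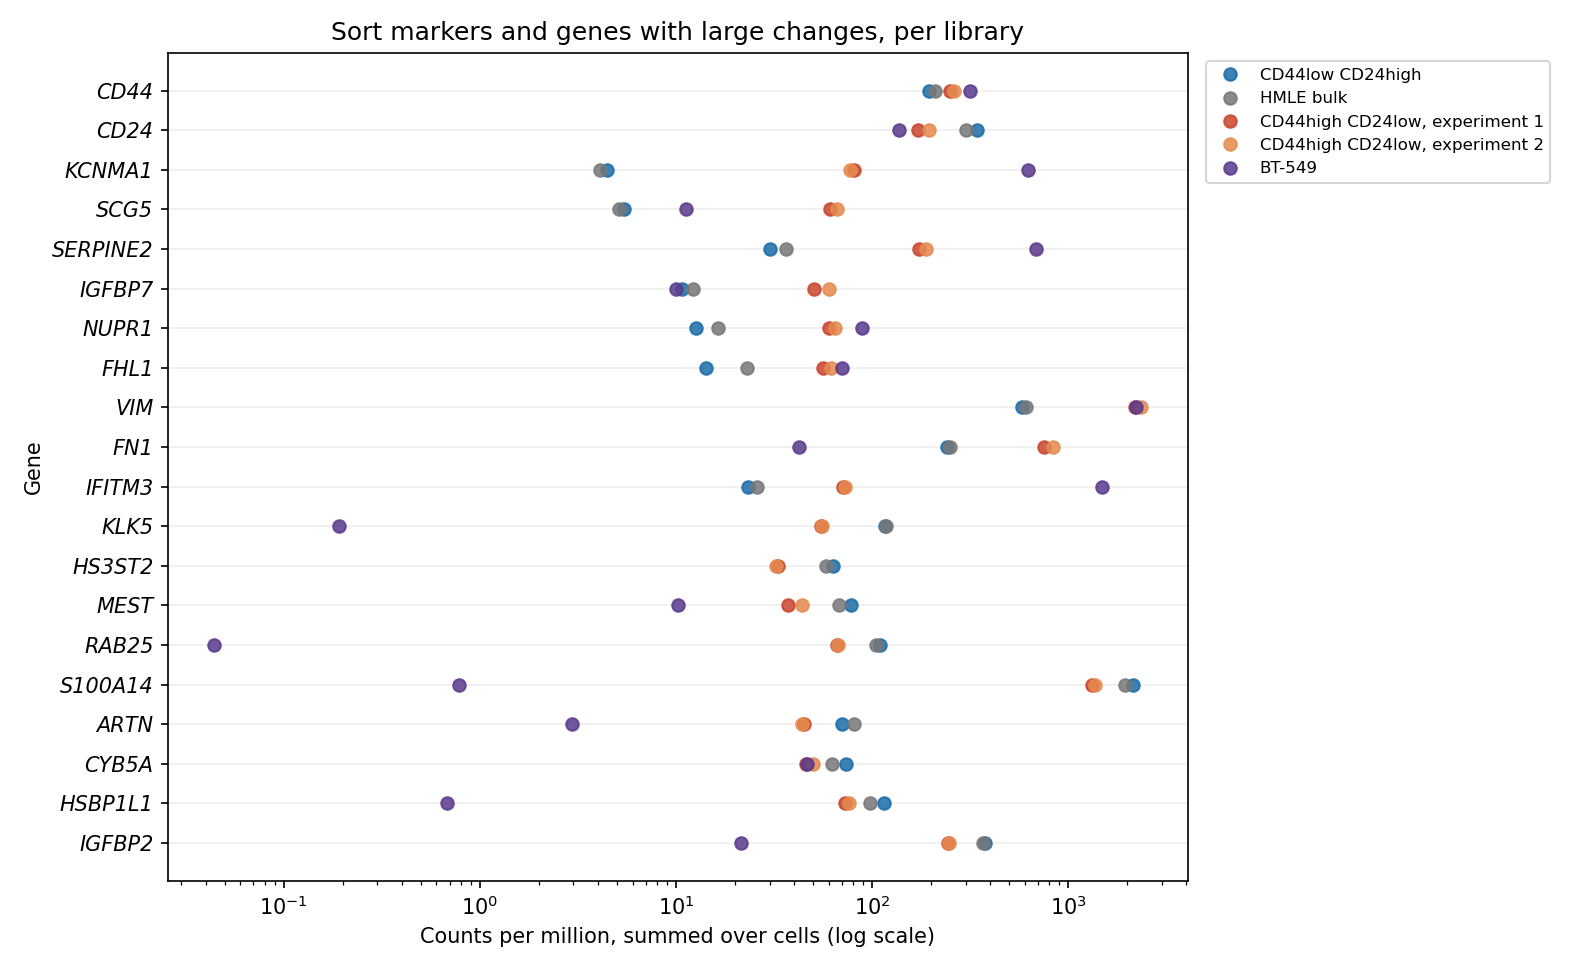
CPM (log axis, summed over cells) of the sort markers and of genes with large rises and falls between the sorted HMLE populations, 1 point per library, with no error bar. The 2 CD44high CD24low experiments lie close together for each gene, KCNMA1 lies at 79.2 CPM on average in them against 4.44 CPM in the CD44low CD24high library, and a library with no count of a gene has no point.

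Mesenchymal and matrix genes rose together. In the mesenchymal list, 29 of 38 tested members rose, 3 fell and 6 did not pass, and 35 passed when adjusted over the list alone. The list median was 2.12, or 1.87 with undetected members at the floor of 3 counts, above all 10000 random lists matched on expression. COL6A2 (chromosome 21), a chain of type VI collagen, had no count in the CD44low CD24high library and 4.97 CPM in the CD44high CD24low libraries, at least 86.9-fold higher, and POSTN (chromosome 13), which encodes periostin, was at least 34.9-fold higher. TNC and PDPN fell by 0.47 and 0.36 on the log2 scale. Among collagens, 12 of 19 rose, 4 fell and 3 did not pass, with 18 past the test adjusted over the list alone. COL5A1 was at least 20.4-fold higher, whereas COL16A1 and COL18A1 changed by -0.58 and -0.50. Of the transcription factors of the epithelial-mesenchymal transition, 7 of 19 rose and none fell, with 7 past the test adjusted over the list alone. PRRX1 (chromosome 1) had no count in the CD44low CD24high library and was at least 51.7-fold higher. ZEB1 (chromosome 10), a repressor of CDH1, went from 2 counts to 5.01 CPM, a ratio of 132 with a counting interval of 35.4 to 1063. In the TGF-beta responsive list 11 of 24 rose and 2 fell, with 14 past the test adjusted over the list alone. LTBP1, a latent TGF-beta binding protein, rose by 3.17, while TGFB2 and PTHLH changed by -0.86 and -0.68. WNT pathway genes went both ways, with 8 of 23 higher, 5 lower and 14 past the test adjusted over the list alone. WNT5B rose by 3.66 and LEF1 by 2.63, and WNT10A and WNT7A changed by -0.86 and -0.69. Without the mesenchymal-like cluster these changes were smaller. Of the mesenchymal list 18 of 36 rose and 3 fell, with a median of 0.55, of collagens 6 of 18 rose and 4 fell, with a median of 0.48, and of the transcription factors 5 of 18 rose. Of TGF-beta responsive genes 8 rose and 2 fell, and of 21 WNT genes 3 rose and 3 fell. LTBP1, WNT5B and LEF1 then rose by 1.54, 1.58 and 2.06. Free RNA from the cluster's cells, weighed below, could give some of these remaining rises. COL6A2 lay at 15.4 and 15.1 CPM in the cluster and at 0.838 and 0.457 CPM in the other CD44high CD24low cells. ZEB1 lay at 13.5 and 16.5 CPM against 0.877 and 0.771 CPM. LEF1 lay above the level that free RNA would add in both experiments, and LTBP1 in experiment 1 only. WNT5B was not among the genes found above it.

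Epithelial genes fell, but by little. In the epithelial junction and polarity list 22 of 35 members fell, 1 rose and 12 did not pass, and 24 passed when adjusted over the list alone. The median was -0.29, below all 10000 matched random lists. RAB25 and the epithelial transcription factor ELF3 changed by -0.73 and -0.71, and EHF was the member that rose, by 0.64. Without the mesenchymal-like cluster, 2 epithelial members rose, 2 fell and 30 did not pass, and the median was -0.02. Basal genes went both ways, with 8 of 29 higher, 6 lower and 14 past the test adjusted over the list alone. Without the mesenchymal-like cluster 8 were higher, 1 was lower and 20 did not pass, with a median of 0.12. The basal keratin KRT14 (chromosome 17) rose from 2297 to 3620 ± 112 CPM (SD, n = 2), a log2 fold change of 0.64, whereas ITGB4 and TRIM29 changed by -0.38 and -0.34. OXTR was called higher by 0.62, but its direction reversed with cells thinned to 5000 UMIs (-0.14) and it did not pass with DESeq2. Of 18 luminal genes 2 rose, 1 fell and 3 passed when adjusted over the list alone: XBP1 and KRT7 rose by 0.47 and 0.30 and KRT8 changed by -0.49, and without the cluster neither keratin passed. In the list of genes associated with breast stem cells, 8 of 20 rose and 1 fell, with 9 past the test adjusted over the list alone. NOTCH3 rose by 1.67, GLI2 had a ratio of 15.6 with a counting interval of 4.05 to 126 (2 counts in the CD44low CD24high library), and ID3 changed by -0.52. CD44, on which the cells were sorted, is a member that rose, so this count is not independent of the sort. Without the mesenchymal-like cluster 4 members of this list rose, 1 fell and 15 did not pass. In the squamous list 2 of 24 rose and 4 fell, with 6 past the test adjusted over the list alone. The squamous median was -0.10, and without the mesenchymal-like cluster it was 0.11, with 1 member higher and 1 lower. With all kept cells, the following values were found. SBSN rose by 1.36, SPRR2A had a ratio of 4.59 with a counting interval of 1.54 to 24.1 (3 counts), and KLK6 and KLK5 changed by -1.10 and -1.08.

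Stress, inflammatory and interferon genes were also higher. In the unfolded protein and amino acid response list 17 of 25 rose, 2 fell and 6 did not pass, with 19 past the test adjusted over the list alone and a median of 0.31. The glutathione-degrading CHAC1 and asparagine synthetase ASNS rose by 1.91 (SE 0.14) and 1.58 (SE 0.080), while the chaperone genes SDF2L1 and CRELD2 changed by -0.37 and -0.20. Of inflammatory and NF-kB genes 14 of 27 rose and 1 fell, with 19 past the test adjusted over the list alone and a median of 0.64. The chemokine gene CCL5 and the cyclooxygenase gene PTGS2 rose by 2.52 and 1.91 from 0.210 and 0.114 CPM, and IL11 changed by -0.45. Of interferon-stimulated genes 9 of 24 rose and none fell, with 9 past the test adjusted over the list alone. The exonuclease gene ISG20 rose by 2.05, and XAF1 had a ratio of 11.7 with a counting interval of 1.84 to 445 (1 count). HLA and antigen presentation genes gave 8 of 17 higher and none lower, with 9 past the test adjusted over the list alone, and PSMB9 and HLA-B rose by 1.51 and 1.44. In the hypoxia and glycolysis list 13 of 30 rose and 2 fell, with 15 past the test adjusted over the list alone. NDRG1 and P4HA2 rose by 1.08 and 0.79 and HK2 and ADM changed by -0.39 and -0.30. Of immediate early and heat shock genes 16 of 28 rose and 1 fell, with 19 past the test adjusted over the list alone. KLF2 rose by 1.17, EGR2 was at least 4.97-fold higher with no count in the CD44low CD24high library, and FOSB changed by -0.33. In the antioxidant list 7 of 24 rose and 1 fell, with 9 past the test adjusted over the list alone. The aldo-keto reductase genes AKR1C1 and AKR1C2 rose by 2.16 and 2.08, values that are uncertain because these near-identical paralogs can share reads, and TXNRD1 changed by -0.28. Without the mesenchymal-like cluster, 16 amino acid response genes, 14 NF-kB genes and 12 hypoxia genes were higher, with medians of 0.32, 0.62 and 0.22. The interferon list then had 3 members higher and 1 lower (median 0.21), the HLA list 5 higher and 1 lower (0.21), the immediate early list 8 higher and 1 lower (0.22) and the antioxidant list 7 higher and 1 lower (0.13). A cluster with the cytokine genes CXCL8 and IL1B among its 10 leading genes held 10.1% and 9.64% of the CD44high CD24low libraries against 5.50% of the CD44low CD24high library, and its part in the NF-kB change was not tested.

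The remaining lists covered contractile, surface, metabolic and cell cycle genes. In the actin list 8 of 23 rose and 2 fell, with 11 past the test adjusted over the list alone. The myosin light chain gene MYL9 rose by 1.31 and ACTA2 by 1.04, and FLNA and CNN2 changed by -0.43 and -0.19, but without the mesenchymal-like cluster MYL9 was at -0.18. In the adhesion and surface list 14 of 29 rose and 4 fell, with 20 past the test adjusted over the list alone. SDC2 was at least 9.31-fold higher and ITGA4 rose by 1.80, and BCAM and L1CAM changed by -0.61 and -0.54. Of cholesterol synthesis genes 6 of 24 rose and 2 fell, with 10 past the test adjusted over the list alone. FDFT1 and MSMO1 rose by 0.34 and 0.31 and TM7SF2 and PMVK changed by -0.38 and -0.21. Of nuclear oxidative phosphorylation genes 3 of 30 rose and 4 fell, with 7 past the test adjusted over the list alone. SDHA and ATP5B rose by 0.50 and 0.40 and NDUFB10 and COX4I1 changed by -0.28 and -0.25. None of the 13 mitochondrially encoded genes rose and 9 fell, with 10 past the test adjusted over the list alone, 1 of them higher. MT-CO3 and MT-CO1 changed by -0.51 and -0.43. Without the mesenchymal-like cluster 4 of the 13 fell and 9 did not pass, with a median of -0.275 against -0.283 with all kept cells. A cluster rich in mitochondrial RNA, with a median of 12.3% mitochondrial UMIs in the CD44low CD24high library, held 10.9% of that library against 0.107% and 0.413% of the CD44high CD24low libraries. In the G1/S list 9 of 42 rose and 14 fell, with 24 past the test adjusted over the list alone. RRM2 and TYMS rose by 0.57 and 0.53 and BLM and PRIM1 changed by -0.46 and -0.43. In the G2/M list 10 of 49 rose and 5 fell, with 15 past the test adjusted over the list alone. CDC25C and NEK2 rose by 0.50 and 0.39 and CENPA and AURKA changed by -0.24 and -0.21. Without the mesenchymal-like cluster 7 G1/S genes were higher and 4 lower, and 3 G2/M genes were higher and 1 lower.

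Some markers of other cell types rose too. Of 9 detected stromal fibroblast markers 5 rose, with 6 past the test adjusted over the list alone. COL1A2 went from 1 count to 6.81 CPM, a ratio of 357 with a counting interval of 65.0 to 14356, DPT was at least 77.9-fold higher at 4.45 ± 1.58 CPM (SD, n = 2), and MEG3 rose by 5.13. COL1A1, chosen after its values were seen, was at 114 ± 27.4 CPM (SD, n = 2) against 2.88 CPM, a log2 fold change of 5.28 that was positive in both experiments but did not pass (adjusted p = 0.10, edgeR quasi-likelihood, Benjamini-Hochberg, with the lone library assumed to vary as the pair did). All 3 tested endothelial markers rose, with 3 past the test adjusted over the list alone: PECAM1 and ROBO4 rose by 2.24 and 2.18 to 0.806 and 6.68 CPM, and EGFL7 by 1.05. FABP4 was the adipocyte marker of 5 that rose, by 6.29 to 6.24 CPM, and LAPTM5 the immune marker of 6 that rose, by 1.90 to 0.586 CPM, each with 1 past the test adjusted over the list alone. The fibroblast list is not independent of the mesenchymal list, since it shares COL1A1, COL1A2, COL3A1, DCN, LUM and PDGFRB with that list. Without the mesenchymal-like cluster, 3 of 7 tested fibroblast markers, 1 of 3 endothelial, 1 of 4 adipocyte and 0 of 6 immune markers were higher.

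**Figure D2:**
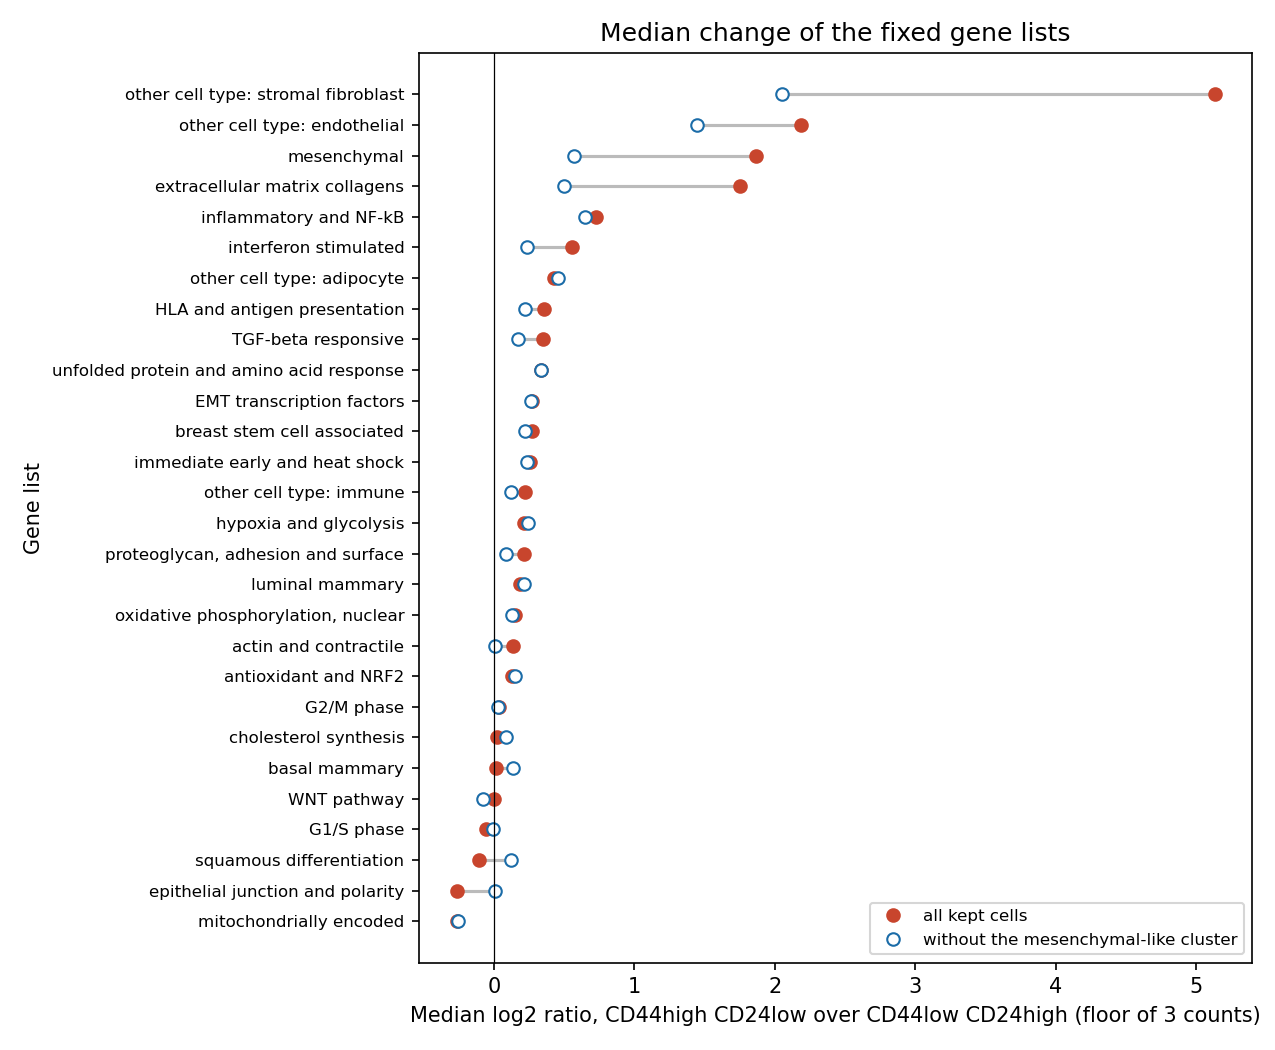
Median log2 ratio of CD44high CD24low over CD44low CD24high for the 28 gene lists, with undetected members at the floor of 3 counts. Filled points use all kept cells and open points leave out the mesenchymal-like cluster, and no error bar is drawn. The mesenchymal median moves from 1.87 to 0.57, and the NF-kB median from 0.73 to 0.65.

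The second comparison asked what the CD44high CD24low sort enriched relative to the HMLE bulk population. Genes with large rises were KCNMA1, SCG5, SERPINE2 and IGFBP7, with log2 fold changes of 4.28 (SE 0.092), 3.63, 2.31 and 2.19. KLK5, the neurotrophic factor gene ARTN, HS3ST2, MEST and CD24 had the largest falls, with log2 fold changes of -1.08 (SE 0.060), -0.85, -0.82, -0.73 and -0.71. In all, 2174 of 16192 genes rose and 1707 fell at an adjusted p under 0.05, 642 and 130 of them at least 2-fold. The largest adjusted p of the genes named here was 5.3e-07, for MEST (edgeR quasi-likelihood, Benjamini-Hochberg), with the lone bulk library assumed to vary as the CD44high CD24low pair did. Without the mesenchymal-like cluster 909 genes passed, and DESeq2 called 847 genes of which 79.8% were higher, against 56.0% with edgeR.

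The third comparison set the CD44low CD24high population against the bulk population, with 1 library each and no replicate check. Both were close. Of 15918 genes with counts enough, 1 was at least 2-fold higher in the CD44low CD24high library and 27 were at least 2-fold lower, and the standard deviation of the log2 ratio was 0.136 over the 7171 best-measured genes, against 0.105 between the 2 CD44high CD24low experiments. The dynein light chain gene DYNLL1 (chromosome 12) was at a ratio of 1.34 (95% counting interval 1.33 to 1.36), and beta-2-microglobulin (B2M, chromosome 15) at 1.30. In every gene list but the immediate early list, which had 1 member higher, each measured member was within 2-fold.

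The bulk population lay near the CD44low CD24high population. Over the 745 genes changed at least 2-fold between the sorted populations, bulk expression was nearer the CD44low CD24high level for 650 (87.2%). A least-squares mixture of the sorted profiles gave a CD44high CD24low share of 5.68% of the bulk profile, and 0.686% when only genes with a log2 fold change of 2 or more were used. Of bulk cells thinned to 5000 UMIs, 20.2% correlated better with the CD44high CD24low profile, against 18.4% of CD44low CD24high cells and 48.7% and 48.8% of CD44high CD24low cells. This class is a range along a score, since 33.2% of bulk cells lay within 0.02 of the dividing line.

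Clustering of all HMLE cells gave 8 clusters. Cluster 5 was called mesenchymal-like because it had the highest mean log2 CPM of mesenchymal minus epithelial markers of the 8 clusters. It had 13 detected mesenchymal markers and was led by COL1A1, CADM3, FBLN5, KCNMA1 and NREP. It held 488 of 1872 CD44high CD24low cells in experiment 1 (26.1%, 95% exact binomial interval 24.1% to 28.1%) and 186 of 726 in experiment 2 (25.6%, 22.48% to 28.96%). It held 3 of 4611 bulk cells (0.0651%) and 0 of 2183 CD44low CD24high cells, with an exact upper limit of 0.169%. Since genes that define the cluster differ between the populations, the clustering was repeated without the 745 genes, which gave 24.3% and 24.1% with 440 of 488 and 174 of 186 cells shared. Without all 4192 called genes it gave 18.6% in both experiments, with fewer cells shared, 339 of 488 and 135 of 186. The sort itself can set these shares. Within the CD44high CD24low libraries the cluster kept KRT14 at 1.18 and 1.41 times the level of the other cells and KRT5 at 0.687 and 0.745 times, whereas EPCAM lay at 0.211 and 0.202 times, CDH1 at 0.227 and 0.233 times and CD24 at 0.362 and 0.354 times. EPCAM and CDH1 are among the epithelial markers of the rule that picked the cluster, so their low levels are partly set by it. Basal markers besides KRT14 and KRT5 also lay lower in the cluster, with TP63 at 0.369 and 0.439 times and CDH3 at 0.362 and 0.375 times. CD44 transcript differed little, at 1.15 and 1.16 times. Cluster 6 was proliferating-like, led by DEPDC1, ARL6IP1, HMMR, AURKA and CCNB1, and held 4.70% to 5.81% of each library. Clusters 1 to 4, 7 and 8 were left unnamed. Cluster 1 was led by FAM195A, HS3ST2 and MEST, cluster 2 by C1orf56, PHKG1 and CTNNB1, cluster 3 by CAMK2B, GPM6B and NDRG1, cluster 4 by CRCT1, SERPINB2 and SPRR2D, cluster 7 by GJA1, PLXNB2 and COL17A1 and cluster 8, with 36 cells, by TIGAR, NT5DC1 and ALKBH4.

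**Figure D3:**
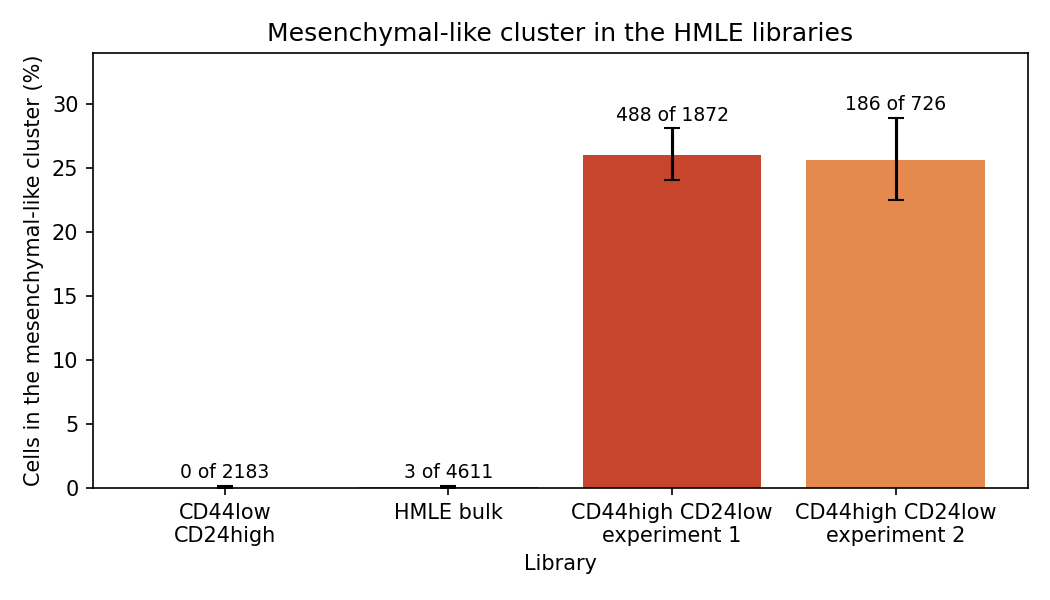
Share of cells in the mesenchymal-like cluster in each HMLE library, in percent, with 95% exact binomial intervals that cover counting error only and the number of cells above each bar. The cluster held 26.1% and 25.6% of the CD44high CD24low cells and at most 3 cells of the other libraries.

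The fourth comparison set BT-549 against HMLE bulk, with 1 library each, so that line, medium and library differ together and no test was made. BT-549 had an interferon and mesenchymal profile with almost no basal keratin. IFI6 (chromosome 1, 27666061 to 27672218), an interferon-induced gene, was at 3213 CPM against 3.44 CPM, 934-fold higher (95% counting interval 865 to 1010), and IFI44L (chromosome 1), with no count in bulk, was at least 25420-fold higher. COL1A2 (chromosome 7), a chain of type I collagen, and CSAG1 (chromosome X) and BAALC (chromosome 8) also had no count in bulk and were at least 18287-fold, 11625-fold and 11415-fold higher. The keratins KRT17 and KRT14 (chromosome 17) and KRT5 and KRT6A (chromosome 12) were 2551-fold, 2625-fold, 3125-fold and 3950-fold lower. The metallothionein gene MT1E (chromosome 16), S100A14 and S100A16 (chromosome 1), the growth factor gene AREG (chromosome 4), SFN (chromosome 1) and RHOD (chromosome 11) were 2074-fold, 2481-fold, 1139-fold, 1309-fold, 1684-fold and 2199-fold lower. Of 17560 genes, 3046 were at least 2-fold higher and 1700 at least 2-fold lower on log2(CPM + 1). The median of all genes was at 0.13, a shift that TMM scaling moved to 0.0022 with 2479 genes higher and 2128 lower, so list medians are read against 0.13.

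All 30 interferon-stimulated genes were at least 2-fold higher in BT-549, with a median log2 ratio of 5.45. BST2, which encodes tetherin, was 8212-fold higher, IFI27 445-fold, MX1 927-fold and ISG15 201-fold, and XAF1, from 5 counts in bulk, 7286-fold. Antigen presentation genes gave 7 of 20 higher and 1 lower, with PSMB9 23.5-fold and HLA-B 9.60-fold higher. Of mesenchymal genes 30 of 39 were higher and 3 lower, with a median of 2.86, and COL5A2, COL6A3 and COL1A1 were 300-fold, 216-fold and 127-fold higher. Of collagens 12 of 19 were higher and 4 lower. Among EMT transcription factors 13 of 19 were higher and 1 lower, with ZEB1 515-fold higher and PRRX1, from 1 count in bulk, at a ratio of 17280 with a counting interval of 3100 to 682613. Fibroblast markers were higher in 9 of 12, and MEG3 was 796-fold higher. FN1 went the other way, at 42.5 CPM in BT-549 against 251 CPM in bulk. TGF-beta responsive genes gave 12 of 24 higher and 5 lower, with IGFBP3 112-fold higher, and WNT genes 12 of 27 higher and 8 lower, with DKK1 90.2-fold lower. Of epithelial genes 32 of 35 were lower and none higher, with a median of -4.25, and SPINT2 and PKP3 were 363-fold and 2090-fold lower. Of basal genes 23 of 29 were lower and 1 higher, with a median of -4.75. Luminal genes gave 7 of 19 lower and 2 higher, with KRT18 356-fold lower, and squamous genes 13 of 24 lower and 1 higher, with CSTA 686-fold lower.

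The remaining lists in BT-549 covered metabolism, signalling, stress and the cell cycle. Cholesterol synthesis genes were lower in 11 of 24 and higher in 1, with a median of -0.76 and MVK 6.04-fold lower. Adhesion and surface genes were lower in 14 of 29 and higher in 5, with ANPEP 340-fold higher and BCAM 43.6-fold lower. Hypoxia and glycolysis genes were higher in 12 of 30 and lower in 3, with ADM 6.79-fold higher. Immediate early genes were higher in 10 of 28 and lower in 3, with JUN 5.31-fold higher. NF-kB genes gave 8 of 29 higher and 9 lower, with CCL2 807-fold higher and SAA1 637-fold lower. Stem cell associated genes gave 7 of 23 higher and 4 lower, with ID3 19.2-fold higher and PROCR 18.5-fold lower. Antioxidant genes gave 4 of 24 higher and 5 lower, with HMOX1 139-fold higher. Actin genes gave 6 of 23 higher and 3 lower, with MYL9 39.0-fold higher, and amino acid response genes 3 of 25 each way, with DDIT3 5.12-fold higher and TRIB3 4.40-fold lower. Nuclear oxidative phosphorylation genes were within 2-fold for 28 of 30 and mitochondrially encoded genes for 13 of 13. G1/S genes were within 2-fold for 35 of 42, with GINS2 3.50-fold lower, and G2/M genes for 41 of 49, with HJURP 2.98-fold higher. Of the immune, endothelial and adipocyte markers, 1 of 6, 2 of 4 and 1 of 6 were higher and 1, 0 and 0 lower, with PPARG 14.2-fold higher and CORO1A 10.6-fold lower.

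BT-549 was also placed between the sorted HMLE profiles. Over the 745 genes, BT-549 lay nearer the CD44high CD24low level for 515 (69.1%): 492 of the 711 genes higher in that population and 23 of the 34 lower ones. No reference share was computed for this. Over the 7171 best-measured genes the correlations of BT-549 with the sorted profiles differed little. They were 0.737 with CD44low CD24high and 0.752 and 0.753 with the CD44high CD24low experiments. KCNMA1, SERPINE2 and VIM were at 622, 682 and 2206 CPM in BT-549, near or above their CD44high CD24low levels, while SCG5 was at 11.3 CPM. Of cell cycle genes, the summed G1/S level ranged from 1760 CPM in BT-549 to 1892 CPM in HMLE bulk, and the summed G2/M level from 3830 CPM in HMLE bulk to 4276 CPM in CD44high CD24low experiment 2. With TMM-scaled CPM the lowest G2/M level was instead that of BT-549, at 3689 CPM against 3930 CPM in bulk. With cells thinned to 5000 UMIs, a UMI of the proliferation gene MKI67 was found in 62.4% of bulk, 63.0% of CD44low CD24high, 55.7% and 57.2% of CD44high CD24low and 41.4% of BT-549 cells, and in 97.1%, 92.6%, 96.0%, 96.4% and 63.6% without thinning. Shares for TOP2A were 31.5%, 32.5%, 30.8%, 31.4% and 28.9%. No cell type that lacks these genes was in the libraries, and 431 BT-549 cells under 5000 UMIs were left out.

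Within BT-549, clustering gave 8 clusters of 1720, 1136, 976, 577, 284, 168, 75 and 50 cells, none of which was named. Cluster 1 was led by CTHRC1, STXBP6 and RGS2, cluster 2 by PCP4, CCL5 and COX7B2, cluster 3 by ALPL, PGF and GAL, cluster 4 by ANK3, CHCHD10 and LINC00665, cluster 5 by CDH6, IQGAP2 and LBH, cluster 6 by SPRR2D, SCG5 and GPNMB, cluster 7 by NEURL3, ETV7 and PSG9 and cluster 8 by MMP1, PLAT and SERPINI1. Median levels of the genes of some chromosomes differed between clusters. In cluster 2 the median log2 ratio to the other BT-549 cells was -0.33 over 168 genes of chromosome 14 and 0.26 over 118 genes of chromosome 22, and in cluster 4 it was -0.42 over 107 genes of chromosome 22.

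**Figure D4:**
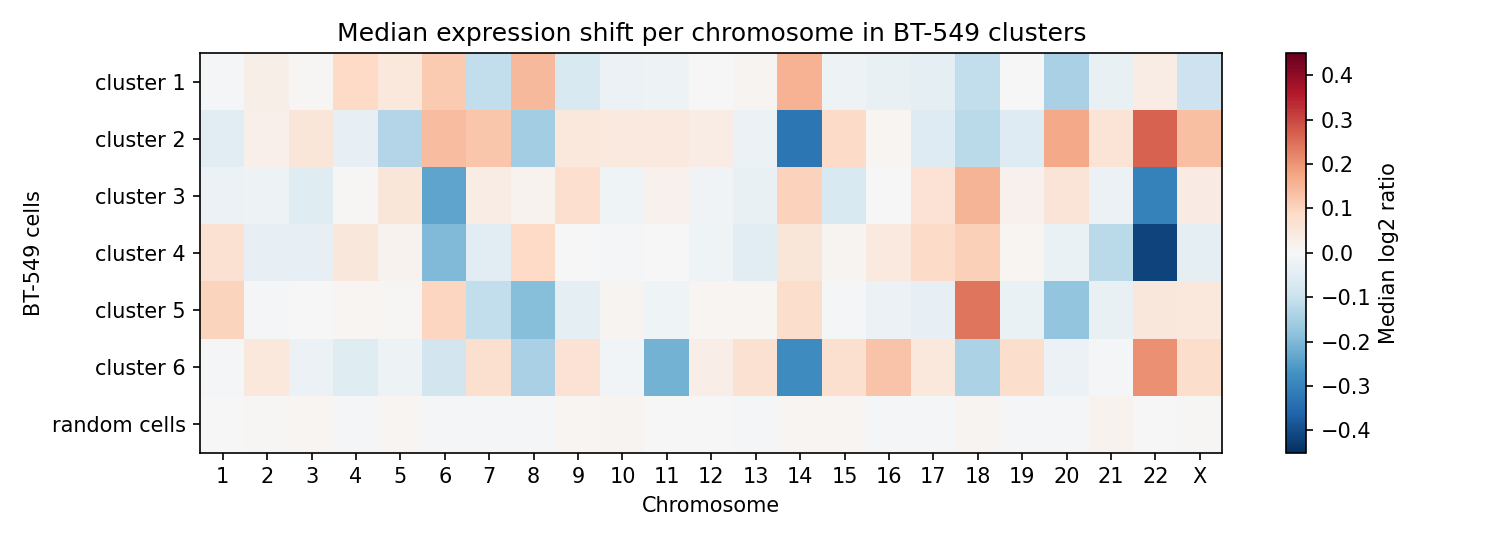
Median log2 ratio of the genes of each chromosome between the cells of a BT-549 cluster and all other BT-549 cells, for the 6 clusters of 150 cells or more and for a random split of the cells. Chromosome 22 lies at 0.26 in cluster 2 and at -0.42 in cluster 4, and the random split stays near 0.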

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

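The alternatives without the mesenchymal-like cluster, without clusters 7 and 8, without high-UMI cells and without called genes were chosen only after the results were seen. No paired analysis was possible because only experiment 1 holds both sorted groups. Of 1586 values over 107 single-gene results between the sorted populations, 1426 stayed the same, 144 were weaker, 13 moved and 3 reversed. The weaker values fell mostly in 4 settings: of the 107 genes, 29 were weaker with DESeq2, 30 with cells thinned to 5000 UMIs, 33 without the mesenchymal-like cluster and 37 without it and without clusters 7 and 8. Weaker in all 4 were PDPN, TRIM29, KLK6, PTGS2, IL11, HK2, ADM, COX4I1, CDC25C, NEK2, CENPA, AURKA, KLF2, CRELD2 and CNN2. KCNMA1, POSTN, NOTCH3, KRT7, KRT8, ITGB4, ACTA2 and MEG3 were weaker only without the mesenchymal-like cluster. The list medians were less stable: 74 of 194 values between the sorted populations moved and 1 reversed, and 62 of 139 moved for BT-549. For CD44high CD24low against CD44low CD24high, 1236 genes were called with DESeq2, 1343 with cells thinned to 5000 UMIs, 1583 without the mesenchymal-like cluster, 1433 without it and without clusters 7 and 8, and 745 with a log2 fold change of 1 or more also asked for. Against bulk these were 847, 1027, 909, 737 and 772. Without cells above 2 times their library's median UMIs, 2931 genes were called between the sorted populations, 2898 of them also called in the same direction with all kept cells, with 17 instead of 34 at least 2-fold lower, and 2652 were called against bulk. The sign of OXTR reversed with thinning (-0.14), and that of MYL9 without the cluster (-0.18, or -0.20 without clusters 7 and 8 too). The actin list median was then -0.0072. With a pseudocount of 5, 1638 genes were at least 2-fold higher and 990 lower in BT-549. The CD44high CD24low share of the bulk profile ranged from 5.07% to 6.23% when either CD44high CD24low library was left out, but was 0.686% for genes with a log2 fold change of 2 or more and 0.753% with plain CPM, so it is known only as small. At 3000 UMIs, 25% of bulk cells lay nearer the CD44high CD24low profile, and the ratios of CD44high CD24low to CD44low CD24high shares were 0.922 for MKI67 and 0.907 for TOP2A. The mesenchymal-like cluster held 0.325% of bulk cells at resolution 1.0. Clustered without the 745 genes it held 0.629% of bulk and 0.321% of CD44low CD24high cells, and without every called gene 18.6% and 18.6% of CD44high CD24low cells. BT-549 gave 5 clusters at resolution 0.3 and 16 at 1.0. Between the mesenchymal-like cluster and the other CD44high CD24low cells, BT-549 lay nearer the cluster for 74.0% of genes, 199 of 316 higher in the cluster and 189 of 208 lower in it. The cause of these shifts was not tested.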

Other observations

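The tests of doublets, of stromal fibroblasts, of free RNA for lower genes and of chromosome medians were chosen only after the result was seen. The others were written before their values were known. Of these, the test of the arms of chromosome 20 was of the chromosome with the largest shift in the mesenchymal-like cluster. The mesenchymal-like HMLE cells had lower levels of most basal markers. The median log2 ratio of 10 basal markers to the other HMLE cells was -1.38, and TP63 lay at 0.369 and 0.439 times the level of the other CD44high CD24low cells. KRT14 was an exception at 1.18 and 1.41 times, while VIM was 4.91 and 4.85 times higher, FN1 4.31 and 4.62 times and ZEB1 15.4 and 21.4 times. VIM, FN1 and ZEB1 are among the mesenchymal markers of the rule that picked the cluster. The other CD44high CD24low cells held a cluster led by CAMK2B, GPM6B and NDRG1, with the serine synthesis genes PSAT1 and PHGDH also among its leading genes. It made up 15.1% and 14.0% of the CD44high CD24low libraries, 4.58% of the CD44low CD24high library and 9.07% of bulk. Its cells held 1.41 to 1.48 times the median UMIs of their library, so depth or cell size differed too.

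Other sources of the mesenchymal-like cluster were weighed. Doublets with epithelial cells would keep epithelial markers, but 6 of them lay at a median of 0.245 and 0.237 times the level of the other cells. Epithelial markers were also part of the rule that picked the cluster, so this outcome is partly set by it. Genes specific to BT-549 lay at 0.00243 and 0.00392 times their BT-549 level (25 genes), which excludes BT-549 cells, and KRT14 at 1.18 and 1.41 times excludes fibroblasts without basal keratin. Chromosome 20 had the largest shift of any chromosome in this cluster, with medians of -0.200 and -0.205 over all its genes. The 20q genes are among these, so their medians are not independent of that shift. Genes of 20q had medians of -0.216 and -0.223, above the -0.25 set as the lower bound for no copy number difference. Their bootstrap ranges, -0.275 to -0.150 and -0.289 to -0.177, reached past that bound, so the cluster may or may not be a subclone. Asking that the whole range clear the bound was decided after the values were seen.

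Differences that remained without the cluster could come from free RNA of its cells in the other droplets. Of 201 genes still at least 2-fold higher, 44 (21.9%) lay at or under the level that the highest free RNA ratio would add in both libraries. The other 157 lay above it in at least 1 of the 2 libraries, and some of them in 1 library only. All 674 genes called lower lay beyond the dilution of -0.17 log2 that free RNA would give, but the smallest fall called was already -0.21, so this outcome was fixed by the calling and the lower genes stay open. Thus, for most of the genes that were at least 2-fold higher, free RNA does not explain the level in at least 1 library. This cannot be extended to the mesenchymal genes. ZEB1, ZEB2 and PRRX1 were not among the 157. CDH11, LOX and COL5A1 were among them, but lay above the level in experiment 1 and not in experiment 2. Only 7 of the 201 genes reached 20 CPM, 6 of them above the level in at least 1 library. Of these, SERPINE2 and NUPR1 lay above it in experiment 1 but not in experiment 2.

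BT-549 clusters differed in the median levels of whole chromosomes, and whether they differ in copy number stays open. In 6 of 6 clusters at least 1 chromosome lay beyond 2 times the largest z of randomly split cells (1.73). Clusters made from expression differ more than random cells in any case, so this test does not tell copy number from other differences in expression. The HMLE mesenchymal-like cluster passed the same bound, with z of -8.73 and -8.47 for chromosome 20 and 4.43 and 3.80 for chromosome 9. A copy number difference of chromosome 20 was left open for that cluster, so it is not a control known to lack one. When the genes of each chromosome were split into 2 sets, the sets correlated across BT-549 cells above random gene sets for 22 of 22 chromosomes, but 21 did so in HMLE bulk cells too, so this second test cannot tell, a reading also set after the values were seen. The median correlation was 0.282 in BT-549 and 0.135 in HMLE bulk. DNA copy number measured in single BT-549 cells would settle it.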
